A study of Mus musculus with 16 samples.

How the data were processed

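Gene expression was measured by RNA sequencing of total RNA in 16 mouse libraries: 11 brainstem tumours of 4 genotypes, 3 samples of normal brainstem and 2 cell lines grown from cortical tumours. Per the labels, the tumours arose after in utero electroporation of the embryonic brainstem, the mice were of the outbred CD1/ICR background, and GFP-marked tumour tissue was dissected before RNA was extracted. The label DNp53 was read as a dominant-negative form of p53. The design text speaks of biological replicates, and nothing beyond that states that replicates came from separate animals or litters.

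The deposited tables hold whole-number read counts per gene, with no normalization by the authors visible in the values: totals differ between libraries. Per the submitters' processing notes, base calls were converted with bcl2fastq, reads were aligned with TopHat to the mouse build mm10, and edgeR was among the tools. The notes give no versions. The counting program, the strand setting and the treatment of reads that match several genes are not stated. Genes with near-identical relatives, such as the Gbp, Tgtp, Iigp, Ifi200 and H2 families, therefore carry uncertain counts, as do overlapping genes. Counts assigned to Pdgfb, Pdgfra, Trp53 and H3f3a cannot be divided into those of the mouse's own gene and those of the electroporated construct. The brainstem counts cover 24454 genes and those of the cortical lines 24541, of which 10 and 2 had no symbol and were kept under their gene number. All columns of values belonged to a labelled sample. Coordinates are given as in the deposited tables, on mm10.

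From the counts, edgeR 4.0.16 in R 4.3.3 was used for the main tests: genes were kept with filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM factors, and the quasi-likelihood F test (glmQLFit, glmQLFTest) was applied. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Tumour against normal brainstem compared the mean of the 4 genotype means with the normal group in a fit of all 14 brainstem libraries, which also gave each genotype against normal. Over both drivers, K27M against H3.3WT was the histone term, and PDGFB against PdgfraD842V the driver term, of an additive model of the 11 tumours. The histone effect within each driver and the difference between these effects came from a model with 1 mean per genotype over the same tumours. Levels are CPM scaled by TMM factors unless counts are given, as mean ± SD. For the 2 cortical lines, levels only are given. Their CPM, those of Casr and those of regional genes were taken from library totals.

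A set of 29 gene lists of cell types and pathways was fixed from textbook knowledge before the data were examined, as were the comparisons, the main settings and the rule for the genes named. Of these lists, 28 were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Members called are counted at the adjusted p over all genes, and also adjusted over the list alone. List means per library are means of log2 CPM with a prior count of 0.5.

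The rule for named genes took the construct genes first. For the comparisons over all tumours it then took up to 10 genes higher and 10 lower with the largest fold changes among those past the threshold. Their libraries had to show no overlap between sides and their mean had to lie above the median of the genes tested. Within 1 driver and for the difference between drivers it took up to 5 and 5. For the difference between drivers there are no 2 sides, so the overlap condition was not applied. Unnamed and predicted genes and microRNA, small nucleolar RNA and ribosomal protein genes were left out. In each list described, up to 4 members with the smallest p were named. Other genes named were chosen after their values were seen, and the text says so.

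The tests were tested on simulated data, counts drawn from the real means and library sizes, with 100 genes changed by 2-fold and 100 by 4-fold in each comparison. For K27M over both drivers, with 15323 genes tested, 22% of the 2-fold and 79% of the 4-fold changes were recovered. For K27M within PDGFB tumours (15669 genes tested) these shares were 1% and 31%, and within PdgfraD842V tumours (15668 genes tested) 3% and 41%. The difference between drivers (15666 genes tested) recovered 0% and 1%. False calls made up 1.94% of 103 calls over both drivers, 8.57% of 35 within PDGFB and 2.22% of 45 within PdgfraD842V tumours. For the difference they made up 0% of 1 call. The changed genes were drawn only from those above a minimum mean count.

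Alternatives planned in advance were DESeq2 size factors, no filter, a filter of at least 5 CPM in 2 libraries, the Wald test of DESeq2 1.42.0, other sets of libraries in the fit, the mean of the neuron and mature oligodendrocyte lists as a covariate, and leaving out each library in turn. A sex term, set by whether Ddx3y or Xist had more counts, and a table without Rn45s and Lars2 were added after the data had been seen. A pseudocount was not varied. The tests of single genes used counts and needed none. Camera used log2 CPM with a prior count of 2, and the correlation of Cdkn2a with Trp53 used a prior count of 0.5.

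Brainstem libraries held 20084427 to 27644677 counts, so the 3 counts that a value of 0 allows correspond to 0.109 to 0.149 CPM. Such limits cover counting error only.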

Results

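The data comprised mouse models of diffuse intrinsic pontine glioma, a childhood tumour of the brainstem. Tumours carried 1 of 2 drivers, the ligand PDGFB or the activated receptor PdgfraD842V, together with dominant-negative p53 and either wild-type histone H3.3 or H3.3K27M, the lysine-to-methionine mutant that inhibits the Polycomb methyltransferase PRC2. There were 2 PDGFB H3.3WT, 3 PDGFB H3.3K27M, 3 PdgfraD842V H3.3WT and 3 PdgfraD842V H3.3K27M tumours, with 3 normal brainstem samples and 2 cortical tumour lines. Total counts were 20825234, 20084427 and 25425085 in normal brainstem and 24557065 and 22999614 in PDGFB H3.3WT tumours. They were 25609446, 26425520 and 22600214 in PDGFB H3.3K27M, 23460215, 22136279 and 27644677 in PdgfraD842V H3.3WT and 25727271, 25675353 and 26259199 in PdgfraD842V H3.3K27M tumours. The cortical lines had 15397070 and 13429489.

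Normal brainstem separated from the tumours on the first principal component, which held 42.9% of the variance, and the drivers separated on the second, with 21.2%. Correlations of log2 CPM between replicates ranged from 0.980 to 0.986 in normal brainstem and from 0.910 to 0.959 in PdgfraD842V H3.3K27M tumours. Sex was unequal between groups. By the counts of Xist, transcribed from the inactive X, and Ddx3y, a Y-linked gene, Ddx3y was the higher in 4 of 5 H3.3WT tumours and in 1 of 6 K27M tumours, and Xist was the higher in all 3 normal samples. The drivers differed too. Among PDGFB tumours only H3.3WT replicate 1 had more Ddx3y, against all 3 PdgfraD842V H3.3WT tumours and PdgfraD842V H3.3K27M replicate 1.

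**Figure D1:**
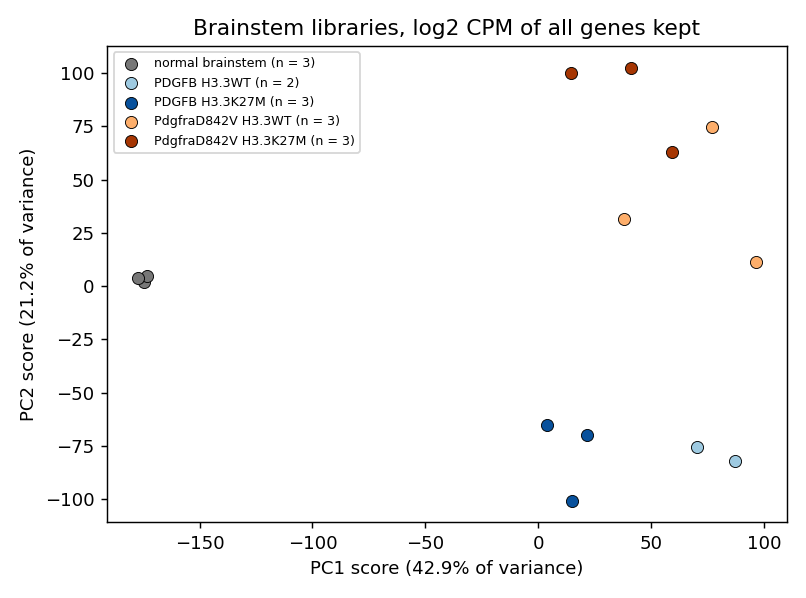
Scores of the 14 brainstem libraries on the first (x axis, 42.9% of variance) and second (y axis, 21.2%) principal components of log2 CPM, coloured by group. The 3 normal samples lie together at the left, and the 5 PDGFB tumours lie below the 6 PdgfraD842V tumours.

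Pdgfb and Pdgfra were each highest in the tumours labelled with that driver. Pdgfra was also above normal brainstem in PDGFB tumours, whose labels name no Pdgfra construct. Trp53 and H3f3a were higher in every tumour group than in normal brainstem. Pdgfb stood at 188 ± 101 CPM (SD, n = 2) in PDGFB H3.3WT and 63.5 ± 23.1 (n = 3) in PDGFB H3.3K27M tumours, against 10.2 ± 3.05 and 16.9 ± 5.01 (n = 3 each) in the H3.3WT and H3.3K27M tumours with PdgfraD842V and 9.97 ± 0.686 (n = 3) in normal brainstem. Pdgfra, the receptor for PDGF ligands, was at 85.5 ± 5.61 CPM in normal brainstem, 1878 ± 117 and 1315 ± 362 in PDGFB tumours with H3.3WT and H3.3K27M, and 3692 ± 1428 and 2986 ± 673 in PdgfraD842V tumours. Trp53 was at 17.6 ± 2.28 CPM in normal brainstem and between 107 ± 31.1 (PDGFB H3.3K27M) and 354 ± 152 (PdgfraD842V H3.3WT) in the group means of tumours. H3f3a, 1 of the genes for H3.3, was at 105 ± 1.94 CPM in normal brainstem, 344 ± 15 and 322 ± 62.2 in the H3.3WT tumours with PDGFB and PdgfraD842V, and 479 ± 46.2 and 441 ± 88.0 in the K27M tumours. Counts do not show which base the histone transcripts carried, so they do not check the mutation itself. The genes lie on chromosomes 15 (Pdgfb, 79995875 to 80014808), 5 (Pdgfra, 75152290 to 75198204), 11 (Trp53, 69580358 to 69591873) and 1 (H3f3a, 180802559 to 180813605).

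**Figure D2:**
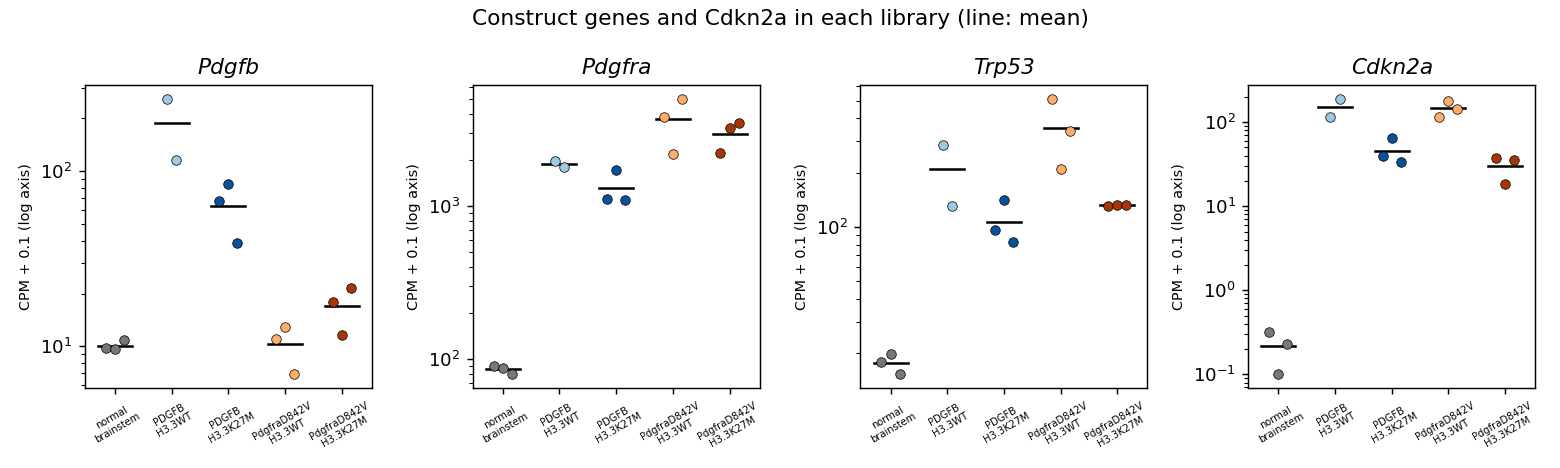
Levels of Pdgfb, Pdgfra, Trp53 and Cdkn2a in each brainstem library (y axis, CPM plus 0.1 on a log scale), by group (x axis), with lines at group means. Cdkn2a lies lower in each of the 6 K27M tumours than in any of the 5 H3.3WT tumours.

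The first comparison asked how the tumours differ from the tissue in which they arose. Tumours had high Cdkn2a, which encodes the p16 and p19Arf tumour suppressors, with a log2 fold change of 9.24 ± 0.58 (SE, 11 tumours against 3 normal samples, adjusted p = 2.97e-07). Markers of neurons and myelin were lower and those of dividing cells, progenitors, microglia and interferon signalling were higher. Cxcl10, an interferon-induced chemokine, rose by 8.67 ± 0.88, Timp1, an inhibitor of metalloproteinases, by 7.32 ± 0.68, and Hmga2, an architectural chromatin protein of fetal tissue, by 6.71 ± 0.58. Slc6a5, the glycine transporter of inhibitory brainstem neurons, had a log2 fold change of -6.79 ± 1.03 and Glra1, the glycine receptor subunit, one of -6.09 ± 0.86. In each of these genes every tumour lay on 1 side of every normal sample, a condition for being named that 68.5% of the called genes met.

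Other large increases were those of Cst7 (6.92 ± 0.53), the tubulin gene Tuba1c (6.84 ± 0.72) and the interferon-inducible genes Ifi47 (6.84 ± 0.77), Batf2 (6.81 ± 0.92) and Ifi204 (6.80 ± 1.07). Zbp1, a sensor of nucleic acids, had 3 counts over the 3 normal samples and 19839 over the tumours, a ratio of pooled rates of 1606 with a 95% exact interval of 550 to 7790 that covers counting error only and not the spread between tumours. Its fitted log2 fold change was 8.70 ± 1.12. The next largest decreases among the genes named were those of Scn4b (-6.04 ± 1.09), Syt2 (-5.81 ± 0.92), Slc24a2 (-5.36 ± 0.61), Lamp5 (-5.35 ± 0.89), Panx2 (-5.27 ± 0.61), Nefh (-5.24 ± 1.11), Vamp1 (-5.07 ± 1.04) and Rph3a (-4.93 ± 0.50). Of the construct genes, Pdgfra rose by 4.73 ± 0.32 (adjusted p = 3.81e-07), Trp53 by 3.35 ± 0.34 (5.36e-06), Pdgfb by 1.92 ± 0.33 (0.000301) and H3f3a by 1.89 ± 0.16 (1.59e-06). Pdgfb passed in 20 of 21 alternatives (adjusted p from 6.21e-09 to 0.0694) and did not with a single term for all tumours.

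All 20 members of the neuron list fell, among them Kcnc1 (-3.14 ± 0.26), Syp (-3.47 ± 0.32) and Gad1 (-3.39 ± 0.33), as did all 18 of the mature oligodendrocyte list, such as Ugt8a (-3.35 ± 0.41) and Fa2h (-4.44 ± 0.60). Of 24 cell cycle genes 22 rose and 2 did not pass, with Ccnb2 at 6.83 ± 0.65 and Top2a at 5.79 ± 0.60. In the oligodendrocyte precursor list 11 of 18 rose, including Vcan (2.42 ± 0.30) and Sox6 (2.70 ± 0.37), 1 fell and 6 did not pass. In the neural stem list 11 of 17 rose and 2 fell, with Nes, an intermediate filament of progenitors, at 4.26 ± 0.28 and Sox4 at 3.45 ± 0.27. The list of targets of PDGF and MAPK signalling had 12 of 20 higher and none lower, led by Dusp6 (2.68 ± 0.15) and Ccnd1 (4.67 ± 0.35). The mesenchymal glioma list had 17 of 19 higher, with Vim at 5.51 ± 0.33 and Socs3 at 5.66 ± 0.41.

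Of the microglia and macrophage list 15 of 16 rose, including Ptprc (2.53 ± 0.21) and C1qc (3.91 ± 0.45), and all 18 interferon response and 15 antigen presentation genes rose, such as Bst2 (5.01 ± 0.61), Irf9 (2.91 ± 0.37), Tap1 (5.38 ± 0.51) and B2m (3.99 ± 0.40). The astrocyte list went both ways, with 3 of 15 higher and 8 lower, among the latter Fgfr3 (-2.03 ± 0.24) and Slc1a2 (-1.92 ± 0.23). Adjusted over the list alone, the counts were 16 for microglia and 23 for cell cycle, and those of the neuron, mature oligodendrocyte, interferon and antigen presentation lists were unchanged. By edgeR, 9787 of 16190 genes differed, 4821 higher and 4966 lower, and 6519 by at least 2-fold. Camera called 15 lists at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.267 with an estimated correlation).

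Against the same normal samples, 8363 genes differed in PDGFB H3.3WT, 7929 in PDGFB H3.3K27M, 9236 in PdgfraD842V H3.3WT and 8398 in PdgfraD842V H3.3K27M tumours. With a sex term these counts were 7589, 7695, 6335 and 7815, so their order changed. All 3 PdgfraD842V H3.3WT tumours had more Ddx3y than Xist, and all 3 normal samples had more Xist. In cell cycle genes 22, 22, 23 and 22 of 24 were higher in these groups, in the order given. Of 18 oligodendrocyte precursor genes 12, 12, 11 and 5 were higher and 0, 1, 3 and 0 lower, and the list's mean log2 CPM was 7.96 to 8.54 in PDGFB tumours, 5.62 to 7.38 in PdgfraD842V H3.3WT and 6.29 to 7.09 in PdgfraD842V H3.3K27M tumours, against 6.09 to 6.13 in normal brainstem. The antigen presentation list differed between groups: 15 of 15 members were higher in PDGFB H3.3WT tumours and in both PdgfraD842V groups, and 2 of 15 in PDGFB H3.3K27M tumours, where 13 did not pass. For the interferon response list the counts were 18 of 18 in those 3 groups and 3 of 18 in PDGFB H3.3K27M tumours. These counts do not test a difference between genotypes, which is given with the histone comparisons.

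The next comparison asked what H3.3K27M changes over both drivers. Casr, the calcium-sensing receptor, had the smallest p of all genes and was chosen after its values were seen: it was at 1.76 ± 0.479 CPM (n = 3) in PDGFB H3.3K27M and 7.45 ± 2.98 (n = 3) in PdgfraD842V H3.3K27M tumours, against 0.0828 ± 0.0556 (n = 2) and 0.184 ± 0.0911 (n = 3) in their H3.3WT counterparts and 2 ± 0.208 in normal brainstem. Its log2 fold change was 4.95 ± 0.46 (adjusted p = 0.0043). Cdkn2a fell by 2.05 ± 0.26 with K27M (adjusted p = 0.031), from 153 ± 52.4 to 45.6 ± 16.4 CPM with PDGFB and from 146 ± 30.7 to 30.4 ± 10.4 with PdgfraD842V. The gene lies on chromosome 4 (89274472 to 89294619). Slc7a3, a transporter of cationic amino acids, fell by 1.39 ± 0.23 (adjusted p = 0.0413).

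Genes higher with K27M were Elovl7, an elongase of long-chain fatty acids (2.07 ± 0.36), the imprinted gene Ndn (1.29 ± 0.19), the membrane protein gene Itm2a (1.25 ± 0.23), Isyna1, which makes inositol (1.15 ± 0.21), Rgl1 (1.09 ± 0.17), the p53 target Ccng1 (0.87 ± 0.15) and Dopey2 (0.70 ± 0.12), with adjusted p between 0.0407 and 0.0494. In each of these, and in Cdkn2a and Slc7a3, all 6 K27M tumours lay on 1 side of all 5 H3.3WT tumours. The rule for named genes required this. Of all 73 genes called in this comparison, 38.4% had it. In the Polycomb list Cdkn2a fell, Igf2bp1 rose (adjusted p = 0.0413), with 1 count over the 5 H3.3WT and 190 over the 6 K27M tumours, and 29 of 31 did not pass. The construct genes did not pass: Trp53 had -1.23 ± 0.27 (adjusted p = 0.0813), H3f3a 0.45 ± 0.15 (0.175), Pdgfra -0.41 ± 0.23 (0.377) and Pdgfb -0.35 ± 0.46 (0.710). Of 19 alternatives, Trp53 passed in 2, DESeq2 and all 14 libraries in the fit (adjusted p from 0.00153 to 0.486), and H3f3a in 1, DESeq2 (0.037 to 0.53).

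Few list members passed. The astrocyte list had 2 of 15 higher, Gfap (2.28 ± 0.43) and Aqp4 (2.37 ± 0.45), and 5 adjusted over the list alone. The mural cell list had 2 of 14 higher, Rgs5 (1.60 ± 0.25) and Vtn (1.66 ± 0.31), and 6 adjusted over the list alone. The blood-brain barrier list, picked after its means were seen, had 1 of 15 higher. Adjusted over the list alone, 8 were higher and 1 lower. Its mean log2 CPM was 5.17 and 5.45 in K27M tumours with PDGFB and PdgfraD842V, and 4.496 and 4.494 in their H3.3WT counterparts. Normal brainstem had 5.27. Every K27M tumour lay above every H3.3WT tumour, and the cause was not tested. The endothelial list overlapped in PDGFB tumours, at 4.24 to 4.59 with K27M and 4.004 to 4.96 with H3.3WT. None of 18 mature oligodendrocyte genes passed over all genes, and 8 were higher adjusted over the list alone, with Cldn11 at 1.91 ± 0.42 (adjusted p = 0.0813 over all genes). The mean log2 CPM of the mature oligodendrocyte list was 4.21 and 3.23 in PDGFB H3.3WT, 3.73 to 7.40 in PDGFB H3.3K27M, 4.46 to 5.74 in PdgfraD842V H3.3WT and 5.36 to 7.42 in PdgfraD842V H3.3K27M tumours, so the ranges overlap within each driver. The cerebellar neuron list, picked after its means were seen, stood at 1.28 to 3.59 in PDGFB H3.3K27M and 1.02 to 3.61 in PdgfraD842V H3.3K27M tumours. In the H3.3WT tumours it stood at -0.330 to 0.318 and 0.290 to 0.834, so K27M and H3.3WT tumours did not overlap. Normal brainstem had 3.08 to 5.08. This list is not part of the normal brain covariate, and the cause of its difference was not tested. Genes of the PRC2 complex and of H3K27 demethylation did not pass in any of 14 cases, with Kdm6b at -0.62 ± 0.22 (adjusted p = 0.196).

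In this comparison edgeR called 73 of 15504 genes, 63 higher and 10 lower. Camera called 17 lists at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.368 with an estimated correlation). The count was 11 with a sex term, 6 with the normal brain covariate, and 1 to 288 when 1 of the 11 tumours was left out, each of which moved it by over 1.5 times. Casr was called in all 19 of these and the other alternatives run for this comparison, with log2 fold changes of 4.63 to 5.30 and adjusted p of 1.04e-18 to 0.0321, while Cdkn2a was called in 10 of 19, with log2 fold changes of -2.21 to -1.77 and adjusted p of 7.86e-10 to 0.107.

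Within PDGFB tumours, K27M was accompanied by low levels of interferon-induced and antigen presentation genes. Gbp4, a guanylate-binding protein induced by interferon, was at 741 ± 477 CPM (n = 2) in H3.3WT and 1.13 ± 0.829 (n = 3) in H3.3K27M tumours, with 1.57 ± 0.174 (n = 3) in normal brainstem. Its log2 fold change was -9.36 ± 1.02 (adjusted p = 0.00347). Iigp1 (-8.50 ± 0.87), Gbp10 (-8.33 ± 0.69), Gbp6 (-8.30 ± 0.67) and Tgtp2 (-9.55 ± 1.20), the last with 6 counts over the 3 H3.3K27M tumours, also fell. These genes encode interferon-inducible GTPases and have close relatives that may share reads. Gbp4, Gbp10 and Gbp6 lie together on chromosome 5 (105115766 to 105293699).

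In the antigen presentation list 9 of 15 fell, 6 did not pass, and 15 fell adjusted over the list alone. Examples are Psmb9, a subunit of the immunoproteasome (-6.05 ± 0.66, adjusted p = 0.00347), the peptide transporter Tap1 (-4.44 ± 0.56), Nlrc5, the activator of class I genes (-7.07 ± 0.92), and B2m, the class I light chain (-3.78 ± 0.49). In the interferon response list 5 of 18 fell, and 17 adjusted over the list alone, with Cxcl10 at -5.06 ± 0.76, Irf9 at -2.95 ± 0.45 and Bst2 at -4.27 ± 0.68. Both lists had the same adjusted p with an estimated correlation (adjusted p = 0.117). None of 13 T and NK cell genes passed and 5 were lower adjusted over the list alone, with Lck at -2.75 ± 0.55 (adjusted p = 0.0748). None of 16 microglia and macrophage genes passed, and the median log2 fold change of that list was -0.00377. In the monocyte-derived macrophage list 1 of 12 fell, Ccr2, the receptor of infiltrating monocytes (-3.64 ± 0.66, adjusted p = 0.0464), and 6 adjusted over the list alone, with a median of -2.12.

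Genes higher with K27M in PDGFB tumours were Dpysl5, of axon guidance (2.44 ± 0.31, adjusted p = 0.00728), and the ephrin receptor Ephb1 (1.86 ± 0.29, 0.0194). Pdgfb itself had -1.57 ± 0.43 (adjusted p = 0.223), Trp53 -0.97 ± 0.40 (0.531), Pdgfra -0.52 ± 0.35 (0.848) and H3f3a 0.47 ± 0.23 (0.658), and of these Pdgfb passed in 1 of 14 alternatives, DESeq2 (adjusted p from 0.0374 to 0.981). Astrocyte genes did not pass over all genes, and 10 of 15 were higher adjusted over the list alone, with Gfap at 2.77 ± 0.65. Mature oligodendrocyte genes did not pass over all genes either, and 10 of 18 were higher adjusted over the list alone, with a median log2 fold change of 3.36. The choroid plexus list stood apart in PDGFB H3.3K27M replicate 2, at a mean log2 CPM of 4.76 against -1.95 to -0.378 in the other 4 PDGFB tumours. EdgeR called 79 of 15921 genes, 6 higher and 73 lower, and 15 to 52 when 1 of the 5 libraries was left out, each of which moved the count by over 1.5 times. The split was less one-sided in some alternatives. DESeq2 called 202 higher and 253 lower, and edgeR on the 2 groups alone 53 higher and 178 lower. With the normal brain covariate edgeR called 13 genes (793 at an unadjusted p under 0.05) and none of the antigen presentation or interferon response genes, whose pooled median log2 fold change was -3.51 with and -4.20 without it, with median SEs of 0.828 and 0.686.

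**Figure D3:**
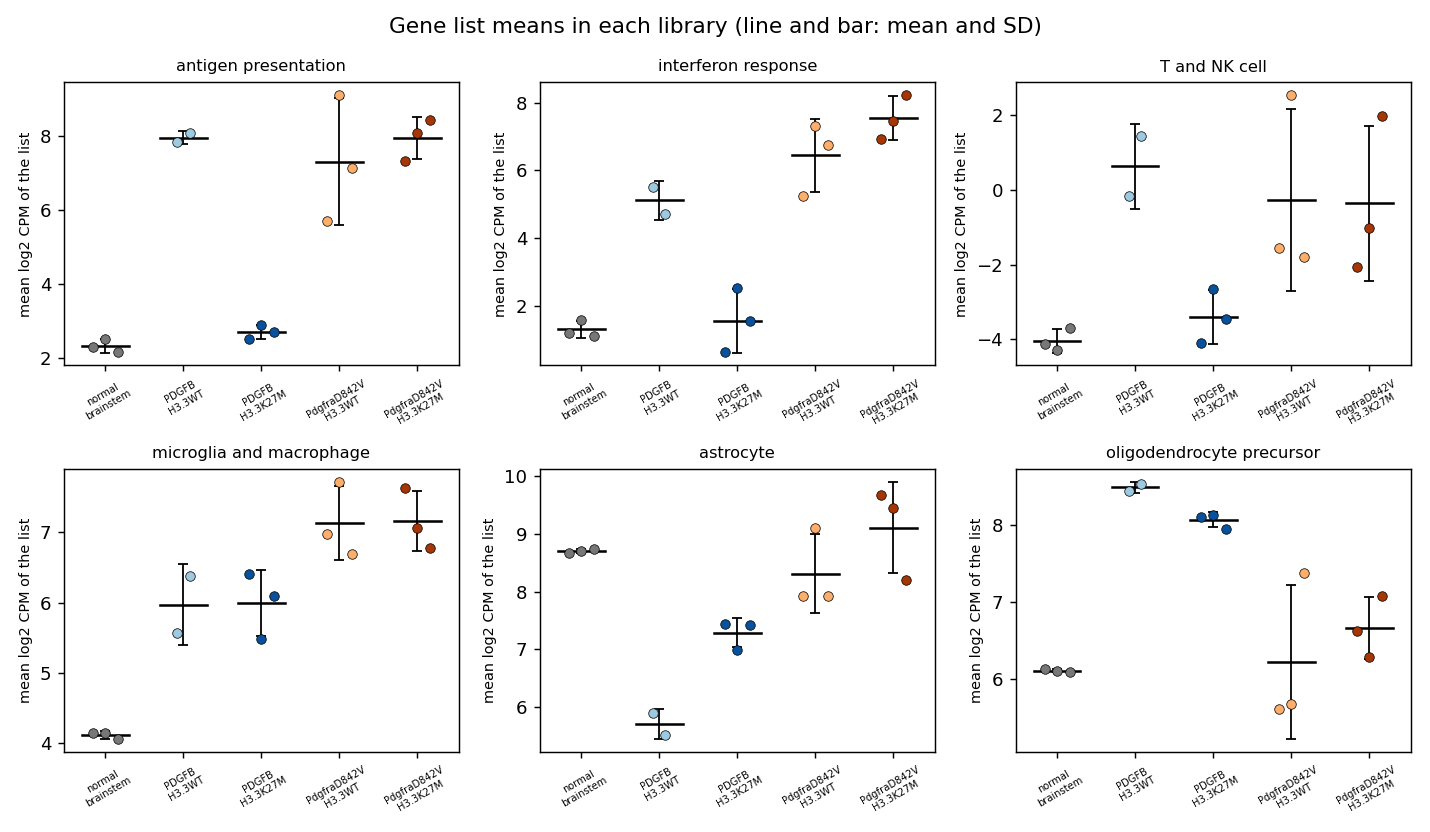
Mean log2 CPM of 6 gene lists (y axis) in each brainstem library, by group (x axis), with lines and bars for group means ± SD. Antigen presentation genes stand at 2.69 ± 0.199 in PDGFB H3.3K27M tumours, beside 7.95 ± 0.166 in PDGFB H3.3WT tumours, while the microglia and macrophage list overlaps between these groups.

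The histone effect differed between the drivers in the same genes. The effect in PdgfraD842V minus that in PDGFB tumours was 9.64 ± 1.4 for Tgtp2 (adjusted p = 0.0231), 9.56 ± 0.83 for Gbp10 (0.00233), 9.52 ± 1.18 for Gbp4 (0.0125), 9 ± 1.03 for Iigp1 (0.00778) and 8.88 ± 1.4 for Plac8 (0.03), a gene of immune cells. It was -6.56 ± 0.95 for the collagen gene Col26a1 (0.0231) and -2.16 ± 0.38 for Dpysl5 (0.0477). In the antigen presentation list 8 of 15 genes differed in this way, and 15 adjusted over the list alone, with Psmb9 at 6.70 ± 0.82, H2-T23 at 5.57 ± 0.87 and H2-K1 at 5.45 ± 0.87. In the interferon response list 1 of 18 passed, and 17 adjusted over the list alone. The T and NK cell and monocyte-derived macrophage lists lay on the same side. T and NK cell genes had a median of 3.995. By edgeR 0 of 13 passed the threshold, and 1 did adjusted over the list alone. The monocyte-derived macrophage list had a median of 1.22, with 1 of 12, and 3 higher and 1 lower adjusted over the list alone. The microglia and macrophage list hardly moved in either driver. Its mean log2 CPM with H3.3WT and K27M was 5.97 and 5.99 in PDGFB and 7.13 and 7.15 in PdgfraD842V tumours. Among the construct genes Pdgfb had 2.29 ± 0.59 (adjusted p = 0.184, and 0.0192 to 0.581 over 19 alternatives, of which it passed with DESeq2), Pdgfra 0.21 ± 0.48 (0.936), Trp53 -0.46 ± 0.54 (0.846) and H3f3a -0.03 ± 0.30 (0.99).

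For this difference edgeR called 61 of 15921 genes, 56 with a higher and 5 with a lower effect in PdgfraD842V tumours. Camera called 9 lists at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.216 with an estimated correlation). The count was 31 with a sex term. Without PDGFB H3.3WT replicates 1 and 2 in turn it was 13 and 16, and without PDGFB H3.3K27M replicates 1, 2 and 3 it was 17, 11 and 4. Without PdgfraD842V H3.3WT replicates 2 and 3 it was 194 and 14, and without PdgfraD842V H3.3K27M replicate 2 it was 20. Of the genes higher with K27M, 6 in PDGFB and 111 in PdgfraD842V tumours, Casr was the 1 shared, against 0.0418 for independent lists. Of the 73 and 41 lower genes none was shared, against 0.188. Calls within 1 driver miss many changes: simulated 4-fold changes were recovered at 31% in PDGFB and 41% in PdgfraD842V tumours. Cdkn2a, lower with K27M in both drivers by group means, was called only in PdgfraD842V tumours. Log2 fold changes of the 2 histone comparisons had a Pearson r of 0.255 and a Spearman rho of 0.266 across 15921 genes, which are not independent replicates.

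Within PdgfraD842V tumours, 5 genes that rose with K27M met the rule for named genes. Dio2, the deiodinase that activates thyroid hormone in astrocytes, was at 357 ± 286 CPM (n = 3) with K27M and 7.40 ± 5.56 (n = 3) without, a log2 fold change of 5.57 ± 0.77 (adjusted p = 0.019). Gdf10, a growth factor of the TGF-beta family, rose by 5.94 ± 1.14, the transglutaminase Tgm1 by 5.03 ± 0.69, Fam107a by 4.25 ± 0.62 and the neuropeptide Npy by 4.04 ± 0.76. Lower genes were Col26a1 (-3.44 ± 0.61), the transferrin receptor Tfrc (-2.63 ± 0.50), Cdkn2a (-2.28 ± 0.36, adjusted p = 0.0306; past the threshold in 9 of 15 alternatives, 3.93e-07 to 0.125), the cadherin Cdh6 (-2.17 ± 0.42) and the glutathione transferase Gstm1 (-1.90 ± 0.36). In each of these genes the 3 K27M tumours lay on 1 side of the 3 H3.3WT tumours, a condition for being named that 100% of the called genes met.

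In the lists, Col3a1 (3.98 ± 0.75) was the 1 of 14 fibroblast and matrix genes that passed, with 6 higher adjusted over the list alone, and Pdgfrb (1.66 ± 0.30), a pericyte receptor, the 1 of 14 mural cell genes. Of 15 astrocyte genes none passed, and 4 were higher adjusted over the list alone. Of 14 endothelial genes none passed, and 8 were higher and 1 lower adjusted over the list alone, with Tek at 1.66 ± 0.49. The PDGF and MAPK target list had no member past the threshold and 6 of 20 lower adjusted over the list alone, with Etv4 at -1.25 ± 0.28 (adjusted p = 0.0631) and Spry1 at -1.25 ± 0.29 (0.0703). Nes fell by 1.47 ± 0.29 (adjusted p = 0.0476). None of the 15 antigen presentation and 18 interferon response genes passed. The construct genes did not pass, with Trp53 at -1.43 ± 0.37 (adjusted p = 0.0823, and 0.00611 to 0.378 over 15 alternatives, of which it passed in 2, DESeq2 and all 14 libraries), Pdgfb at 0.71 ± 0.40 (0.338), H3f3a at 0.44 ± 0.20 (0.25) and Pdgfra at -0.32 ± 0.32 (0.603).

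EdgeR called 152 of 15921 genes in PdgfraD842V tumours, 111 higher and 41 lower. Camera called 11 lists at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.695 with an estimated correlation). Fitted on these 6 libraries alone edgeR called 0, with 2234 genes at an unadjusted p under 0.05 (DESeq2 on all tumours called 1650), and with a sex term it called 5, none of them a gene named here for PdgfraD842V tumours: Col9a1, Elovl7, Kazn, Lrrc55 and Rab3b, chosen after their values were seen. Sex was unequal in these tumours, all 3 H3.3WT tumours and 1 of 3 K27M tumours having more Ddx3y than Xist. The count was 790 without K27M replicate 3, 27 and 28 without K27M replicates 2 and 1, and 50 and 51 without H3.3WT replicates 1 and 3.

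The last comparison set the drivers against each other over both histones. PDGFB tumours had more transcripts of oligodendrocyte precursors and of matrix, and PdgfraD842V tumours more of astrocytes and microglia. Pnlip, pancreatic lipase, was at 342 ± 179 CPM (n = 2) and 180 ± 38.7 (n = 3) in PDGFB tumours with H3.3WT and H3.3K27M and at 0.446 ± 0.601 and 0.791 ± 0.647 (n = 3 each) in PdgfraD842V tumours, a log2 fold change of 8.55 ± 0.72 (adjusted p = 0.000108). Meox1, a mesodermal homeobox gene, rose by 5.32 ± 0.31 and the glutamate receptor gene Gria3 by 4.03 ± 0.23 in PDGFB tumours (adjusted p = 1.87e-05 for both). Col6a5, a collagen VI chain, was at 0.358 ± 0.257 and 0.469 ± 0.606 CPM in PDGFB tumours and at 254 ± 272 and 1517 ± 1875 in PdgfraD842V tumours, a log2 fold change of -10.79 ± 1.34 (adjusted p = 0.00052).

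Further genes higher in PDGFB tumours were the gelatinase Mmp9 (6.79 ± 0.60), Fam184b (4.82 ± 0.67), Col6a3 (4.82 ± 0.67), Vit (4.81 ± 0.75), Fam163a (4.47 ± 0.28), Col3a1 (4.22 ± 0.77) and Postn (4.09 ± 0.52). Those higher in PdgfraD842V tumours included the islet peptide Iapp (-9.13 ± 1.41), the interferon-inducible Apol9a (-6.35 ± 1.10), Gbp8 (-6.20 ± 1.63) and Gbp11 (-5.98 ± 1.59), the B-cell chemokine Cxcl13 (-6.07 ± 1.24), the vitamin D receptor Vdr (-5.50 ± 0.80), Mamdc2 (-5.46 ± 0.45), Phf11d (-5.32 ± 0.94) and Epsti1 (-5.24 ± 0.83). Each of these separated the 5 PDGFB from the 6 PdgfraD842V tumours, a condition for being named that 49.9% of the called genes met. Among the construct genes Pdgfb was higher by 2.96 ± 0.48 (adjusted p = 0.00172) and Pdgfra fell by 1.10 ± 0.23 (0.00673) in PDGFB tumours, while Trp53 (-0.51 ± 0.27, 0.181) and H3f3a (0.11 ± 0.14, 0.607) did not pass.

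Of the oligodendrocyte precursor list 12 of 18 were higher with PDGFB and none lower, including Cspg4 (3.38 ± 0.39), Lhfpl3 (2.46 ± 0.34) and Vcan (1.65 ± 0.25). Of the astrocyte list 13 of 15 were lower, such as Fgfr3 (-3.44 ± 0.37), Aldh1l1 (-4.43 ± 0.57) and Gfap (-3.10 ± 0.44). The microglia and macrophage list had 14 of 16 lower, with Ptprc at -1.42 ± 0.22 and Tmem119 at -2.10 ± 0.39, and the interferon response list 15 of 18, with Ifit3 at -4.73 ± 0.84 and Irf7 at -4.92 ± 1.07. Adjusted over the list alone the counts were 13, 14, 16 and 17. The interferon response result is an average over histones whose effect differed between drivers: the list's mean log2 CPM was 5.52 and 4.71 in PDGFB H3.3WT and 5.24 to 7.33 in PdgfraD842V H3.3WT tumours, which overlap, and 0.619 to 2.51 against 6.94 to 8.23 in the K27M tumours. Of 14 fibroblast and matrix genes 8 were higher, such as Dcn (2.60 ± 0.41) and Lum (4.59 ± 0.76). In the PDGF and MAPK target list 10 of 20 were higher and 4 lower, led by Ccnd1 (3.04 ± 0.28), Spry1 (2.20 ± 0.26) and Dusp6 (1.26 ± 0.16). In the p53 target list 10 of 19 were higher, with Eda2r at 2.71 ± 0.33 and Zmat3 at 1.54 ± 0.21, and 2 lower, among them Fas (-2.74 ± 0.29). The mesenchymal glioma list had 8 of 19 lower, with Socs3 at -2.81 ± 0.27. With the sex term 4 of the 16 microglia genes were lower.

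By edgeR 4260 of 15504 genes differed between drivers, 1945 higher and 2315 lower with PDGFB. Camera called 12 lists at the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.592 with an estimated correlation). With a sex term 2326 genes were called. Sex was unequal between the drivers in these tumours.

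The 2 cortical tumour lines, labelled PdgfraD842V with dominant-negative p53, were grown as neurospheres and are given as levels only, since culture and tissue cannot be separated from genotype. They had Pdgfra at 3583 and 3330 CPM and Pdgfb at 1 and 0 counts, where 0 counts allows up to 0.223 CPM. Olig2, a transcription factor of the oligodendrocyte lineage, was at 809 and 730 CPM, Sox10 at 346 and 600 and Mki67, a marker of cycling cells, at 540 and 290. Mbp, a myelin protein, differed between the lines, at 14.2 and 553 CPM. Ptprc, the common leukocyte antigen, had 0 and 4 counts. Cdkn2a stood at 165 and 205 CPM.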

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

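The tests of the microglia and macrophage, monocyte-derived macrophage and T and NK cell lists, and the tests of sex and normal brain content for the genes called over both drivers were chosen after the results were seen.

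The effect of H3.3K27M differed between PDGFB and PdgfraD842V tumours by a test of the difference itself, for 61 genes. It was 9.64 for Tgtp2, 9.56 for Gbp10, 9.52 for Gbp4, 8.996 for Iigp1 and 8.88 for Plac8 (log2, effect in PdgfraD842V minus effect in PDGFB tumours), and -6.56 for Col26a1 and -2.16 for Dpysl5. In the 2 cortical tumour lines, which enter no comparison, all 18 interferon response and 15 antigen presentation genes had more than 3 counts in both libraries, above the limit that a count of 0 allows. The bar is low: 16 of 20 neuron and 13 of 15 astrocyte genes also passed it, and 6 of 16 microglia and macrophage genes. Mean log2 CPM differed between the lines, at 4.27 and 6.57 for interferon response and 3.74 and 6.45 for antigen presentation. Ptprc, which leukocytes express, had 0 and 4 counts in these lines.

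The antigen presentation and interferon response genes, pooled (33 genes), had a median log2 fold change of -4.20 with K27M in PDGFB tumours, with a median SE of 0.686, and 14 were called. The microglia and macrophage list had a median of -0.00377 (SD 0.752, 16 genes), which argues against a loss of the cells it marks, and with a sex term the pooled median was -4.41 (SE 0.801, 11 called), which argues against sex as the whole cause. With the normal brain covariate it was -3.51 (SE 0.828): most of the fold remained, but 0 were called, the fold being smaller and the SE larger (by DESeq2 without the covariate, 14 antigen presentation and 16 interferon response genes were called). Fewer monocyte-derived macrophages (median of that list -2.12, SD 1.99, 12 genes, 1 called lower over all genes and 6 adjusted over the list alone) and fewer T and NK cells (median -4.60, SD 2.70, 13 genes, 0 called by edgeR) may contribute and cannot be told apart from an effect of the genotype, since both medians lie on the side of the pooled genes and the members spread widely.

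For the 73 genes called between K27M and H3.3WT tumours over both drivers, the median absolute log2 fold change was 2.05, with a median SE of 0.342. The median ratio of the fold change with to that without a sex term was 1.07 (median SE of the ratio 0.215), and with the normal brain covariate 0.956 (median SE of the ratio 0.204). Neither removed the fold changes, but the median SE rose to 0.410 and 0.404, and 9 and 4 of the genes were called. Litter, batch, position of the tumour and content of blood vessels were not tested.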

How the results depend on the processing

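The sex term and the fits without Rn45s and Lars2 were chosen after seeing the data. No named gene past the threshold, in the main settings or in an alternative, had the other sign in the other of these 2 fits.

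The count of genes called for K27M over both drivers was 1016 with DESeq2, 420 with all 14 libraries in the fit, 6 with the normal brain covariate and 11 with a sex term, against 73. Within PDGFB tumours it was 455 with DESeq2, 142 with all 14 libraries, 13 with the normal brain covariate and 231 with the 2 groups alone, against 79. Within PdgfraD842V tumours it was 1650, 1091 and 54 in the first 3 of these, 5 with a sex term, and with the 2 groups alone edgeR called 0 (2234 at an unadjusted p under 0.05), against 152. For the difference between drivers it was 398 with DESeq2, 171 with all 14 libraries and 31 with a sex term, against 61. For PDGFB against PdgfraD842V it was 2326 with a sex term, against 4260. The cause was not tested.

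Camera called 15 lists for tumour against normal brainstem, 17 for K27M over both drivers, 17 in PDGFB and 11 in PdgfraD842V tumours, 9 for their difference and 12 between drivers at the preset correlation, and 0 in each with an estimated correlation.

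When 1 library was left out, the counts ran from 8247 to 10062 for tumour against normal brainstem, from 3179 to 4688 between drivers, from 1 to 288 for K27M over both drivers, from 15 to 52 within PDGFB and 27 to 790 within PdgfraD842V tumours, and from 4 to 194 for their difference. Where this left a group with 1 tumour, that tumour was assumed to vary like the other groups. The lowest were without PDGFB H3.3K27M replicate 3 for PDGFB tumours and for the difference, and the highest over both drivers and within PdgfraD842V tumours were without PdgfraD842V H3.3K27M replicate 3.

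For the named genes, 1561 of 1777 values kept their side of the threshold, 209 no longer passed and 7 newly passed. These values pool all comparisons and include construct genes that did not pass in the main settings. They do not describe the genes called for K27M alone. Cdkn2a, for example, passed in 10 of 19 alternatives over both drivers and in 9 of 15 within PdgfraD842V tumours. Of the 1777 values 8 had the other sign, all in 4 results of construct genes that passed in neither fit: Pdgfb for K27M over both drivers, and H3f3a, Pdgfra and Trp53 for the difference between drivers. Filters, DESeq2 size factors and the removal of Rn45s and Lars2 moved no count of genes by over 1.5 times. No paired analysis was possible because replicate numbers only follow label order. A gene with 0 counts in a brainstem library could stand at up to 0.109 to 0.149 CPM.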

Other observations

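The test of Mtap was chosen after the result was seen; that of the relation of Cdkn2a to Trp53 was not.

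PdgfraD842V H3.3K27M replicate 3 differed from the other 10 tumours in regional genes, chosen after their values were seen. Emx2 was at 18.0 CPM against at most 7.84, and Lhx2 at 62.7 against 1.99 to 15.1. Hoxa2, a hindbrain gene, had 1 count, against 3.01 to 33.7 CPM in the other tumours. Few counts of other HOX genes were not particular to this library: PDGFB H3.3WT replicate 1 had 2, 1, 2 and 0 counts of Hoxb2, Hoxb3, Hoxb4 and Hoxb5. In PDGFB H3.3K27M replicate 2, the choroid plexus and ependyma list had a mean log2 CPM of 4.76.

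Cdkn2a was lower in K27M than in H3.3WT tumours. A chromosomal loss spanning Cdkn2a and Mtap would lower both, but Mtap had a log2 fold change of 0.0925 ± 0.185 (edgeR adjusted p = 0.816), against -2.05 ± 0.26 for Cdkn2a, and Cdkn2b one of -0.40 ± 0.29 (0.486). A smaller loss stays open. Less dominant-negative p53 might also lower Cdkn2a. Over the 11 tumours, Cdkn2a and Trp53 had a Pearson r of 0.628 (permutation p = 0.0406, adjusted over 2 relations 0.0812) and a Spearman rho of 0.600 (permutation p = 0.0566), with r = 0.598 without the 2 farthest tumours. After removal of the driver and histone means, r was -0.127 (permutation p = 0.709) and rho -0.145 (permutation p = 0.674), with r = 0.0229 without the 2 farthest, so the relation cannot be told apart from the groups themselves.

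For tumour against normal brainstem, in a fit with 1 tumour term, 7871 genes were called. The highest other of 100 splits called 31 and only the real split called as many, which argues against chance as the source. For PDGFB against PdgfraD842V, split within each histone, the real split called the most (4260, highest other 3310, 1 of 100). This also argues against chance. In both cases the 100 splits were a draw of those possible, so others could call more. For K27M over both drivers, split within each driver, the real split also called the most (73, highest other 66, 1 of 100). The margin was narrow there and leaving out any 1 tumour moved the count, so chance is not excluded. No splits were made for PDGFB H3.3WT against normal brainstem, for K27M within PDGFB tumours or for the difference between drivers. The 10 splits of 3 against 3 are too few for a share under 0.05: the counts were 7929, 9236 and 8398 for PDGFB H3.3K27M, PdgfraD842V H3.3WT and PdgfraD842V H3.3K27M against normal brainstem, with a highest other of 0 each (edgeR, 1 of 10 as large), and 152 for K27M in PdgfraD842V tumours, with a highest other of 171 (2 of 10 as large).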
